A study of Mus musculus with 8 samples.

How the data were processed

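RNA of mouse mammary epithelial cells made to overexpress ZNF217, a zinc finger transcription factor, was compared with RNA of cells carrying a vector on 8 arrays printed with long oligonucleotide probes (the mouse MEEBO set). Of these, 3 arrays held primary mammary epithelial cells and 5 held SCp2, an established mouse mammary epithelial cell line. Per the labels, the vector RNA was in the Cy3 channel and the ZNF217 RNA in the Cy5 channel on every array, so no dye swap was made. The series' design text names the vector RNA of each cell line as the reference. The groups and replicate numbers were taken from the sample labels.

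The authors deposited 1 table with 1 value per probe and array, taken here as a log2 ratio because the values lay on both sides of 0, between -4.58 and 3.23. The values were read from a text copy of that table made for this work. Whether the blanks and repeated values described in the results were in the authors' table or arose in the copy was not determined. The log base, the direction of the ratio, the background correction, the filters and the normalization were not given in the sources used here. A positive value was read as likely higher with ZNF217, from the dyes in the labels and the use of vector RNA as the reference. No scanner intensities were used here, so the signal over background behind each value is unknown, and the number of arrays limits the precision. The labels do not say whether replicates were separate cultures, so p-values measure only the spread between these samples, which may be technical.

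Each array was centred on its median. Probes with at least 2 of 3 primary and 3 of 5 SCp2 values were tested, which left 20101 of 34968 probes. A mean per cell type was fitted to all 8 arrays with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, so that both cell types shared the estimate of the spread. Each mean was tested against 0, as were their difference (SCp2 minus primary) and their average, in 2-sided tests with Benjamini-Hochberg adjustment and a threshold of 0.05. A ratio against 0 leaves out the spread of the vector cultures. It also holds any dye effect specific to a probe, whereas a dye effect that is equal on all arrays cancels in the difference between cell types. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

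The files do not pair the probe identifiers with genes. The mouse gene table given for this work (RefSeq genes of GRCm38.p6) held 0 of these identifiers, so results are given per probe. For that reason the 37 gene lists chosen before the data were examined had 0 named members and were not tested, the probe of Zfp217, the mouse counterpart of ZNF217, was not analysed here, and no check of the overexpression itself was made. The rule for items to name was also fixed before the data were examined. It took, per cell type, the 10 largest rises and 10 largest falls among probes past the threshold with the same sign on every array with a value. For the difference it took the 6 largest in each direction without overlap between the cell types' values, and where fewer than 5 items passed, the 5 smallest p-values. As the identifiers carry no gene, only the first 2 that rose and the first 2 that fell in SCp2 cells are named, and the rest are given as counts and ranges.

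The fit was tested on simulated log ratios with 200 changed probes among 20101, over 5 runs. For a change of 1 on the log2 scale it found 96.8% of the changed probes in primary cells, 98.0% in SCp2 cells and 72.8% for the difference. For a change of 0.5 it found 23.4%, 42.4% and 2.0%. False calls made up 4.91%, 5.65% and 6.03% of the calls. The simulated columns were independent and held no repeated values, unlike the table described in the results. These shares therefore need not hold for the calls reported here.

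Alternatives fixed before the data were examined were no centring, scaling to 1 median absolute deviation, quantile normalization, stricter and looser limits on missing values, robust variance estimates, array weights, other thresholds, a fit within each cell type, a block for the replicate number, and leaving out each array. Further alternatives were chosen after seeing the data. These counted repeated primary values once (with and without centring), kept only probes with 8 values and unequal primary columns 2 and 3, centred within probes of equal numbers of SCp2 values, and left out SCp2 columns 4 and 5.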

Results

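The data comprised log ratios of ZNF217-overexpressing over vector RNA from 3 arrays of primary mouse mammary epithelial cells and 5 arrays of SCp2 cells. Neither the log base nor the direction of the ratio was given, so folds and the words rose and fell take the values as log2 and as ZNF217 over vector, the direction that the dyes in the labels make likely. If the ratio ran the other way, every rise given here would be a fall of the same size, every fall a rise, and the shares of rises and falls would change places. The comparisons ask which probes have a log ratio away from 0 in each cell type, and which do on average over both. A further comparison asks which differ between the 2 cell types. An average can pass through a change in a single cell type, so it does not test for a change in both. Of the 34968 probes, the 3 primary columns of the table held values for 99.3%, 92.0% and 89.6%, and the 5 SCp2 columns for 88.7%, 76.2%, 59.0%, 40.0% and 20.9%. The column medians before centring were 0.03, 0.00 and 0.01 in primary cells and -0.01, -0.05, -0.04, -0.05 and -0.05 in SCp2 cells. The SD over probes ranged from 0.25 to 0.35.

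The blanks and some values of the table followed a pattern that bears on every replicate statement. In the SCp2 columns, 0 cells held a value to the right of a blank, where blanks placed independently would give 18039 such cells. Primary columns 2 and 3 held exactly the same value in 8329 of 30932 probes (26.9%), against 446 probes in the neighbouring 0.01 step of their difference. In all 408 probes with primary column 2 blank and column 3 filled, column 1 equalled column 3. Such a repeat was present in 3652 of the tested probes (18.2%). Columns are therefore named by their number, and a column may not hold 1 array at every probe. Over the 6774 probes with 8 values and unequal primary columns 2 and 3, the correlation across probes was 0.209 between primary columns 1 and 2, 0.0233 between 1 and 3, and 0.67 between 2 and 3. It was 0.753 between SCp2 columns 1 and 2, and between 0.00548 and 0.23 for every pair of SCp2 columns that included column 4 or 5. At these probes all 3 primary values had the same sign in 47.9% and all 5 SCp2 values in 20.4%. Independent columns with the same shares of positive and negative values would give 35.7% and 10.3%. The fit treats the columns as independent replicates. At probes with a repeat, it counts the same primary value as a further replicate. The neighbouring step held 446 probes, so chance equality can account for few of the 8329. At most probes with a repeat the primary n is therefore too large and the spread is understated. If the closely correlated columns are not independent at the other probes either, the n given below is too large there too and the p-values are too small.

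In SCp2 cells, 468 of 20101 probes had a mean log ratio past the threshold, of which 201 rose and 267 fell. Without a dye swap, a change with ZNF217 cannot be told from a dye effect specific to a probe in these calls. The largest rise was that of mSQ020191, which was 3.75-fold higher with ZNF217, with a mean log2 ratio of 1.91 ± 0.47 (SD, n = 5) and values from 1.11 to 2.30 (limma, adjusted p = 0.000105). mSQ019473 was 3.64-fold higher, at 1.87 ± 0.73 (SD, n = 4, limma adjusted p = 0.00372). Among probes with the same sign in every filled SCp2 column, the largest falls were those of mSQ021396, 2.54-fold lower at -1.35 ± 0.62 (SD, n = 3, limma adjusted p = 0.0172), and mSQ006117, 2.45-fold lower at -1.29 ± 1.12 (SD, n = 5, limma adjusted p = 0.0446). The mSQ006117 values ranged from -2.48 to -0.20. Its mean was -1.01, -0.99, -1.34, -1.56 and -1.55 without SCp2 column 1, 2, 3, 4 or 5, so its size depends on single columns.

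**Figure D1:**
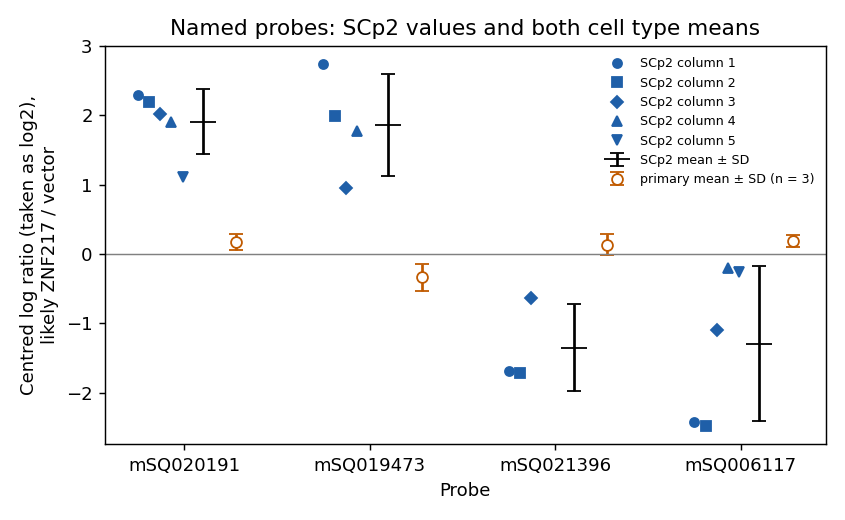
Centred log ratio (taken as log2, likely ZNF217 over vector) of the 4 named probes. Blue symbols are the single SCp2 columns, black lines their mean ± SD, and open orange circles the mean ± SD of 3 primary values. The SCp2 values of mSQ020191 lie between 1.11 and 2.30, whereas the primary means of all 4 probes lie between -0.34 and 0.19.

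In primary cells the same 4 probes had mean log2 ratios of 0.17 ± 0.11 (mSQ020191), -0.34 ± 0.20 (mSQ019473), 0.13 ± 0.15 (mSQ021396) and 0.19 ± 0.09 (mSQ006117; SD, n = 3 each), and none passed the threshold there. The 10 largest SCp2 rises by the naming rule spanned mean log2 ratios of 1.01 to 1.91, with primary means from -0.56 to 0.17. The 10 largest falls spanned -1.35 to -1.01, with primary means from -0.27 to 0.20. Most called changes were small, with a median size of 0.50 on the log2 scale, and 24 probes (12 up, 12 down) changed by 1 or more. The sign was equal in every filled SCp2 column for 457 of the 468 probes, which a call on the mean favours.

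The SCp2 count rested on the spread shared with the primary arrays, on single columns and on the centring. In a fit of the SCp2 arrays alone, 10 probes passed (9 up, 1 down), and neither mSQ021396 (adjusted p = 0.0965) nor mSQ006117 (adjusted p = 0.113) was among them. It was 142, 36 and 91 without primary column 1, 2 or 3, which enter through the shared spread, 12, 20 and 21 without SCp2 column 1, 2 or 3, and 1083 and 1139 without SCp2 column 4 or 5. Falls made up 50.7%, 36.1% and 49.5% of the calls without primary column 1, 2 or 3. Their share was 16.7%, 10%, 66.7%, 67.3% and 65.7% without SCp2 column 1, 2, 3, 4 or 5. Of the 468 probes, 7 (6 up, 1 down) passed in all 8 of these fits, mSQ020191 and mSQ019473 among them. mSQ021396 lost its call without SCp2 column 1 (adjusted p = 0.0955) or 2 (adjusted p = 0.123), at mean log2 ratios of -1.18 and -1.16. mSQ006117 lost its call without primary column 1, 2 or 3 (adjusted p = 0.06, 0.0797 and 0.0643) and without SCp2 column 1, 2 or 3 (adjusted p = 0.154, 0.179 and 0.0814). Without centring, 1562 probes passed and 78.4% of them fell (337 up, 1225 down), against 57.1% with centring. Scaling to 1 median absolute deviation gave 284 probes, of which 70.1% fell (85 up, 199 down). Centring within probes of equal numbers of SCp2 values, a setting chosen after seeing the data, gave 709 probes, of which 46.1% fell (382 up, 327 down).

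In primary cells, limma called 0 of 20101 probes. The smallest adjusted p was 0.0646, and 1503 probes (587 up, 916 down) lay under 0.1. At an unadjusted threshold of 0.05, 4722 probes passed (1805 up, 2917 down), against 1005 by chance. A repeated value was present in 25.5% of these 4722 probes and in 18.2% of all tested probes. With each repeat counted once, a setting chosen after seeing the data, the count was again 0, the smallest adjusted p was 0.11, and 3622 of 19952 probes passed unadjusted. The 5 probes with the smallest p were not past the threshold, each at an adjusted p of 0.0646, and 4 of them carried a repeated value. Without primary column 1 the count was 2. Quantile normalization gave 810 probes (371 up, 439 down), and array weights gave 13159, with a weight of 17.4 on primary column 2.

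The response differed between the cell types for 12 probes. In 11 of them the log ratio was higher in SCp2 cells, by 0.83 to 2.20, and in 1 it was lower, by -1.06 ± 0.14 (SE), with a primary mean of 0.28 and an SCp2 mean of -0.78 (limma adjusted p = 0.0351). mSQ019473 had a difference of 2.20 (limma adjusted p = 0.0351) and mSQ020191 of 1.73 (limma adjusted p = 0.0275). The differences of mSQ021396 and mSQ006117, both -1.48, did not pass (limma adjusted p = 0.0917 and 0.197). The values of the 2 cell types did not overlap in any of the 12 probes, and their means had opposite signs in 11. Both are in large part built in, since a call on the difference favours them. Of the 12 probes, 9 were also called in SCp2 cells. An equal dye effect on all arrays cancels in this comparison, but the calls rested on single columns. The count was 1, 3 and 0 without primary column 1, 2 or 3, 0, 1 and 3 without SCp2 column 1, 2 or 3, and 24 without SCp2 column 4. Few of the 12 were called again, with 0, 1 and 0 without primary column 1, 2 or 3, and 0, 1 and 1 without SCp2 column 1, 2 or 3. The differences of mSQ019473 and mSQ020191 thus lost their calls without primary column 1 or 3 or SCp2 column 1. At an unadjusted threshold of 0.05, 3051 probes passed (1932 higher, 1119 lower in SCp2 cells). Among adjusted calls the larger share of higher ratios turned with at least 1 value per cell type and 3 in all (8 higher, 11 lower). It also turned, on very few calls, without primary column 1 (0 higher, 1 lower) and without SCp2 column 3 (1 higher, 2 lower). It did not turn with quantile normalization (32 higher, 9 lower).

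**Figure D2:**
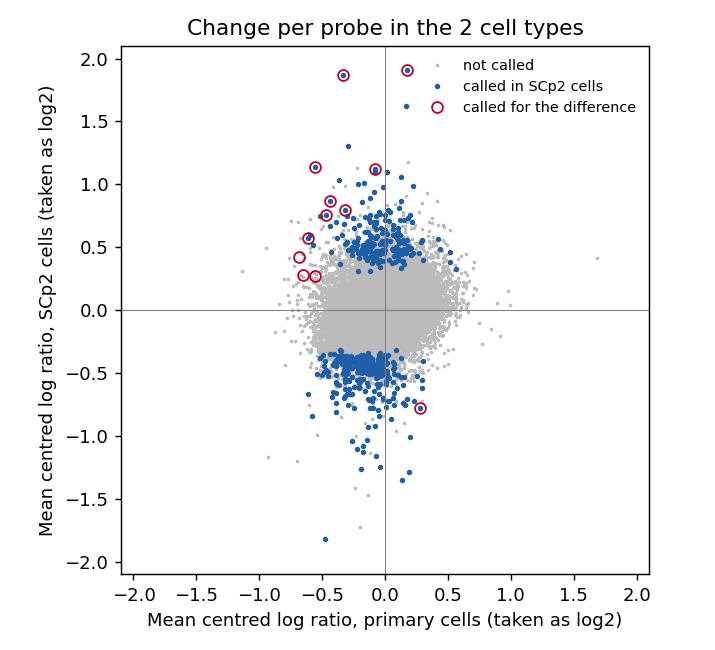
Mean centred log ratio of each of the 20101 tested probes in primary cells (x axis) and SCp2 cells (y axis), both taken as log2. Blue points are the 468 probes called in SCp2 cells and red circles the 12 called for the difference, of which 11 lie higher in SCp2 cells.

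Averaged over both cell types, 1767 probes had a mean log ratio past the threshold, of which 534 rose and 1233 fell (69.8%). Without a dye swap, these calls also hold any dye effect specific to a probe. The larger share of falls turned with centring within probes of equal numbers of SCp2 values, which gave 1363 probes, of which 46.4% fell (730 up, 633 down). The changes had a median size of 0.31 on the log2 scale and reached 1.15. Of these, 214 of the rises and 684 of the falls passed an unadjusted threshold of 0.05 in both cell types. Both cell type means had the same sign in 523 of the rises and 1219 of the falls, which is in large part built in, since a call on the average favours means of the same sign. Of the 1767 probes, 69 rises and 185 falls were also called in SCp2 cells. With repeated primary values counted once, 548 probes passed (116 up, 432 down), all among the 1767. The average count was 800, 0 and 0 without primary column 1, 2 or 3, 1 and 0 without SCp2 column 1 or 2, and 2810 without SCp2 column 4.

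Across the 20101 probes, which are not independent replicates, the mean log ratios of the 2 cell types correlated with r = 0.273 and rho = 0.322, and 13126 (65.3%) had the same direction. The cell types had separate vector references but shared the dye orientation. Since 0 probes were called in primary cells, no overlap of calls could be formed. Of the 267 SCp2 falls, 221 (82.8%) had a negative primary mean, compared with 61.3% of all tested probes. Of the 201 SCp2 rises, 75 (37.3%) had a positive primary mean, compared with 38.7% of all tested probes. After centring within probes of equal numbers of SCp2 values, these shares were 71.3% of 327 falls (52.3% of all) and 58.9% of 382 rises (47.7% of all). In the fit of probes with 8 values and unequal primary columns 2 and 3, they were 87.1% of 217 falls (78.7% of all). For the rises of that fit they were 40.3% of 62 (21.3% of all). Both settings were chosen after seeing the data.

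The log ratios shifted with the number of SCp2 values of a probe. From probes with 2 SCp2 values to probes with 5, the median fell from 0.06 to -0.05, from 0.06 to -0.10 and from 0.12 to -0.18 in primary columns 1, 2 and 3, and from 0.09 to -0.27 and from 0.03 to -0.28 in SCp2 columns 1 and 2. The SCp2 calls followed it, with 62 rises and 36 falls among the 6320 tested probes with 3 SCp2 values, 85 and 72 among the 6487 with 4, and 54 and 159 among the 7294 with 5. For the average of both cell types these were 231 and 158, 201 and 324, and 102 and 751.

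**Figure D3:**
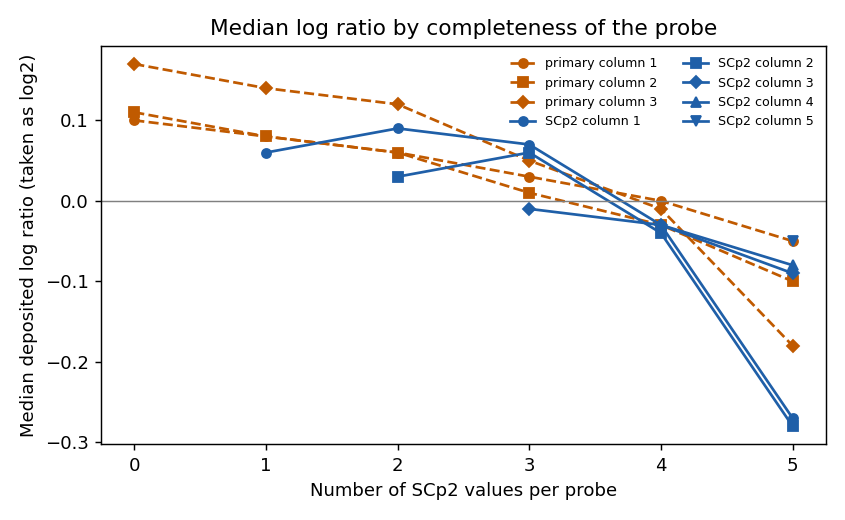
Median deposited log ratio (taken as log2, not centred) of each column, against the number of SCp2 values of the probe, from 0 to 5. Dashed orange lines are the 3 primary columns and solid blue lines the 5 SCp2 columns, and SCp2 columns 1 and 2 reach -0.27 and -0.28 at probes with 5 values.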

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

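The tests of how the table was made were chosen after the pattern was seen, and the test of a dye effect and the counts over other groupings before. The test of a filter was changed after its value of 0.021 had been seen. It had first been read as excluding a stricter filter on each later array, and was then divided into a filter on each array's own spots, judged by the cells to the right of a blank, and a single ranking, left open.

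The 12 probes whose response differed between SCp2 and primary cells were taken up because the difference itself passed its test. Of the 56 splits of the 8 columns into 3 and 5, 3 gave as many probes, so chance is not excluded for this count. The highest other split, SCp2 columns 1, 2 and 3 against the rest, gave 96 probes. Its rest holds all 3 primary columns and SCp2 columns 4 and 5, which are filled in part. Every tested probe has a value in SCp2 columns 1 to 3. At the 6320 tested probes with 3 SCp2 values this split is the same as the split by cell type. Its count therefore cannot tell a structure of the samples, or of the table, from the cell type itself. The median of SCp2 column 1, -0.01, lay apart from the other 4 SCp2 columns (-0.05 to -0.04), with a gap of 0.75 of the range. It was 1 of 10 groups of values examined in this way, and chance marks about 1 in 20 where values are independent and untied. These medians had ties at -0.05, so that rate need not hold for them. The 5 SCp2 medians, also used for the centring, were taken over unlike sets of probes. Over the 7325 probes with 5 SCp2 values they were -0.27, -0.28, -0.09, -0.08 and -0.05, so column 1 did not stand alone there.

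For the 468 probes called in SCp2 cells, the 16 assignments of the 2 channels are too few for a share under 0.05. The real assignment, 1 of 16 with as many, gave 468 and the highest other 124. In primary cells all 4 assignments gave 0 probes, and 4 assignments are again too few. For the average over both cell types, 1 of 100 assignments drawn, the real one, gave 1767 probes and the highest other 1229. This does not exclude chance, although a share under 0.05 had been set as doing so, because the assignments treat the columns as independent and 18.2% of the tested probes carry a repeated primary value. Such counts say nothing on a dye effect, which follows the real assignment.

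The nested SCp2 blanks and repeated primary values bear on every comparison. A filter on each SCp2 array's own spots, with the columns intact, would leave cells with a value to the right of a blank, and there were 0. Values moved left past blank cells when the table was made, by the authors or in the copy used here, may account for the SCp2 blanks. SCp2 columns 1 and 2 would then mix arrays at incomplete probes. Their correlation fell by 0.449 from probes with 5 SCp2 values (0.771) to probes with 2 (0.322), though not to probes with 4 (0.776). Such a move alone would not repeat values in the primary columns. It would also not leave the 408 probes with primary column 2 blank and column 3 filled. A single ranking of probes with a stricter limit for each later array stays open for the SCp2 blanks, since primary columns 2 and 3 lost only 0.021 over the same probes but a ranking by SCp2 signal need not touch them. No biological explanation was tested.

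Log ratios were lower at probes with more SCp2 values in both cell types. A brightness-dependent dye effect common to all arrays predicts this in every primary column, and the differences between probes with 5 and 2 SCp2 values were -0.11, -0.16 and -0.30, with a median of -0.16. The test takes the number of values as a stand-in for brightness, which was not measured here. An effect of ZNF217 itself on transcripts measured more completely stays open and untested, as there is no dye swap. A test of an offset in SCp2 columns 1 and 2 alone was void, since column 5 holds values only at probes with 5, and its outcome is not used.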

How the results depend on the processing

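The settings on repeated values, on 8 values with unequal primary columns, on centring by number of SCp2 values, on leaving out SCp2 columns 4 and 5, and arrays 1 to 3 without the block were chosen after seeing the data. mSQ019473 and mSQ021396 had no value in the settings that kept only probes with 8 values. The 4 named probes kept their direction in every alternative that gave them a value. mSQ020191 and mSQ019473 also stayed past the threshold in every alternative that gave them an adjusted p (limma adjusted p up to 0.00588 and 0.0433). mSQ021396 lost its call in 3 of these and mSQ006117 in 9. The stricter threshold of 0.01 is not in these counts. In the main fit mSQ021396 and mSQ006117 did not pass it (limma adjusted p = 0.0172 and 0.0446). Counts and the correlation are given below where they moved by over 1.5 times or beyond their spread. Except where named, the cause was not tested.

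Probes called in SCp2 cells (468) numbered 1562 without centring, 284 with scaling to 1 median absolute deviation, 1007 with quantile normalization, 287 for probes with 8 values, 133 with at least 1 value per cell type and 3 in all, 2044 with array weights, 8 at an adjusted p under 0.01, 24 with a change of at least 1, and 10 in a fit of SCp2 arrays alone. They numbered 1411 with repeats counted once and no centring, 279 for probes with 8 values and unequal primary columns 2 and 3, 709 with centring by number of SCp2 values, and 2650 without SCp2 columns 4 and 5. Leaving out each array gave 12 to 1139.

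Probes called in primary cells (0) numbered 810 with quantile normalization, 1 with at least 1 value per cell type and 3 in all, 13159 with array weights, 7 with centring by number of SCp2 values, and 464 without SCp2 columns 4 and 5. Leaving out each array gave 0 to 2. The array weights did not converge and put 17.4 on primary column 2.

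Probes called for the difference (12) numbered 41 with quantile normalization (32 higher, 9 lower in SCp2 cells). They numbered 3 for probes with 8 values and 0 at an adjusted p under 0.01. Array weights gave 4280 of them (2242 higher, 2038 lower). With at least 1 value per cell type and 3 in all they numbered 19 (8 higher, 11 lower). They numbered 5 with repeats counted once and no centring, 6 for probes with 8 values and unequal primary columns 2 and 3, and 201 without SCp2 columns 4 and 5. Leaving out each array gave 0 to 24. With the replicate number as a block over arrays 1 to 3 of both cell types they numbered 382, and 233 over the same arrays without the block. The deviations of same-numbered samples correlated at -0.12, -0.021 and -0.12, and no sample correlated best with its own number. As a column may not hold 1 array at every probe, this cannot tell whether same-numbered samples belong together.

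Probes called on average (1767) numbered 989 for probes with 8 values, 9178 with array weights, 0 at an adjusted p under 0.01, 4 with a change of at least 1, 548 with repeats counted once, 916 for probes with 8 values and unequal primary columns 2 and 3, and 4385 without SCp2 columns 4 and 5. Leaving out each array gave 0 to 2810. The correlation across probes (0.273) was 0.225 over called probes alone (-0.133 within the SCp2 rises and -0.144 within the falls, so the pooled value comes from joining probes chosen at both signs), 0.216 for probes with 8 values and unequal primary columns 2 and 3, and 0.224 with centring by number of SCp2 values, and 0.228 to 0.281 leaving out each array.

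As the values were tested per probe, testing single probes in place of gene means is the fit reported, and the alternatives for gene lists and Zfp217 were not run. The signal over background is unknown.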
